A study of Zea mays with 12 samples.

How the data were processed

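The samples were laser-captured root cells of maize (a cross of A188 and B73 by the labels), grown in a greenhouse in sand and turface. Seedlings aged 2 weeks were inoculated with 1000 stage-2 juveniles of Meloidogyne incognita. Giant cells (about 40 to 60 cells per sample) and control cells from parts of infested roots without nematodes (about 75 to 150 cells) were captured at 14 and 21 days, with 3 biological replicates per group and 12 arrays in all. Per the labels, RNA was isolated with the PicoPure kit, amplified with the NuGEN WT-Ovation Pico kit, labelled with biotin with the NuGEN FL module, and hybridized to the Affymetrix maize array, 1 array per sample. Scan dates, batches, the target of the scaling and the version of the software are not given in the sources used here.

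The deposited values are intensity, as MAS5 signals on a linear scale that the authors computed with Affymetrix Expression Console. The values were checked for scale: they are positive and linear, and the trimmed mean of each array was 500.1 or 500.2, so the authors scaled every array to a common trimmed mean. Of 17734 probe sets, 113 are the manufacturer's controls and were left out of the gene tests, and 17621 remained. Detection calls were not used here. Background subtraction beyond that of MAS5 was not applied, and signals near the bottom of the scale are mostly background.

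An offset of 9.5, the 10th percentile of all deposited signals, was added to each signal before log2, which compresses folds of genes that are dim in a group. No further normalization between arrays was applied. Probe sets were tested where the signal was above the 40th percentile of its own array on at least 3 arrays, which removed 5541 and left 12080. A model with a mean for each of the 4 groups was fitted with limma 3.58.1 (lmFit and eBayes with a variance trend) in R 4.3.3, and 6 contrasts were tested: giant against control cells as the mean of both days, at 14 days and at 21 days, the difference of that effect between days, and 21 against 14 days in giant cells and in control cells. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested in each contrast, and the threshold was an adjusted p of 0.05. Errors beside log2 fold changes are standard errors from that fit, and n is the number of arrays. Ratios of 3′ to 5′ signal and the brightness of control transcripts were compared between cell types by exact two-sided permutation of the cell-type labels within each day, over 7 measures. On simulated data, drawn from a normal distribution with the mean and spread of each of the 12080 probe sets tested, 189 of 200 changes of 2 log2 units, 83 of 200 of 1 unit and 0 of 200 of 0.5 units were recovered in the mean contrast. With 3 arrays per group at 14 days, 157, 25 and 0 were recovered. Only 200 probe sets were changed, whereas 5092 and 3324 were called in these contrasts of the data. The adjusted threshold was thus stricter on simulated data, so smaller changes could pass in the data and these shares are not its power.

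The annotation given with the platform names a single gene for 1452 probe sets and several for 1. The other 16168 have no gene in it and were tested without a name. The 1452 probe sets name 1108 genes, of which 1060 are in the RefSeq gene table of the B73 reference assembly used for symbols and synonyms. That table was used for names alone, so no positions are given. Of these genes 978 have a symbol or synonym other than a placeholder. The probe set with the highest mean log2 signal stood for a gene, and 790 named genes were tested.

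Named genes were chosen by a rule fixed before the data were examined. For the mean contrast it takes the 12 largest rises and 12 largest falls among genes past the threshold whose giant-cell arrays all lay above, or all below, the control arrays of the same day. For each other contrast it takes the 5 largest rises and falls, with groups that do not overlap, or the 3 with the smallest p where none passed, and from each gene list up to 4 members with the smallest p. Genes with a description were to come first. The tables used hold no descriptions, so a symbol or synonym other than a placeholder took that role. Where a gene beyond these is named, it is a called member of its list or was chosen after its values were seen.

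Before the data were examined, 33 gene lists were fixed, which cover metabolism, cell wall, hormones, stress, growth and markers of other root tissues. They were matched on symbols and synonyms. No named gene matched 2 of them, ubiquitin and proteasome and the markers of endodermis and cortex. A further 23 list members had names that belong to another kind of gene. They were kept, and the lists were tested without them as an alternative. Lists with at least 5 tested genes, 19 in all, were tested against the other genes with camera (limma) at a preset correlation of 0.01, with 1 probe set per gene, and adjusted over the 19 lists of a contrast. Camera with an estimated correlation and fry were run beside it. In the mean contrast and for the differences between days, none of the camera calls held with an estimated correlation. With fry, which tests whether the genes of a list move on balance in the same direction and does not compare them with other genes, 8 lists passed in the mean contrast. For the difference of the giant-cell effect between days none passed with fry, and the smallest adjusted p was 0.13.

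Whether arrays with the same replicate number belong together was checked from the correlation of their deviations from the group means. It ran from -0.072 to 0.235 for arrays of the same number and from -0.269 to 0.196 for arrays of different numbers. The model had been fixed without pairing, because the labels name no block, and a fit with the numbers as a block was an alternative.

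Alternatives fixed before the data were examined were other offsets (0, or the 40th percentile), quantile normalization, scaling to a common 75th percentile, no filter, a stricter filter (above the median on at least 6 arrays), no variance trend, robust variance estimation, array weights, a fit of the compared groups alone, a replicate block, 1 probe set per gene, a fold of at least 2, and leaving out each array in turn. After the data were examined, scaling to the bacterial and phage hybridization control transcripts, leaving out the day-14 arrays numbered 3 of both cell types, lists without members of another kind, and 3 further gene lists were added. The number of calls in each contrast, and the number of lists past the threshold in the mean contrast and for the difference between days, were also set against other splits of the arrays.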

Results

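Gene expression was measured in maize root cells cut out by laser capture at 14 and 21 days after seedlings were inoculated with the root-knot nematode Meloidogyne incognita, which induces enlarged feeding cells, called giant cells, in the roots of its hosts. Giant cells were set against control cells from regions of the infested roots that held no nematodes. Each of the 4 groups (control cells at 14 days, control cells at 21 days, giant cells at 14 days, giant cells at 21 days) had 3 arrays, described as biological replicates. The labels do not tie an array of control cells to the plant of an array of giant cells. A control sample came from about 13000000 square micrometres of tissue, a giant-cell sample from about 5000000, so the captured area differed with the cell type. Each array carried 17621 probe sets besides the manufacturer's controls, and 12080 were bright enough to be tested. Median signal ran from 182.2 to 229.9 across the 12 arrays, and the number of arrays limits the precision.

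Giant cells and control cells separated along the first principal component, which held 51% of the variance. Pearson correlations across probe sets, which are not independent replicates, ran from 0.844 to 0.934 between arrays of a group. Between giant-cell and control arrays they ran from 0.657 to 0.817. Bacterial and phage control transcripts, which are added at hybridization in equal amounts, were brighter on giant-cell arrays by 0.70 on the log2 scale (1.63-fold, n = 6 against 6, exact permutation p = 0.005, adjusted p = 0.012 over 7 control measures, the smallest p the 400 permutations can give). The 18S ribosomal RNA probe sets were brighter by 0.80 with the same exact permutation p, and the ratio of 3′ to 5′ actin signal was lower in giant cells by -1.77 log2 units, again with an exact permutation p of 0.005. The same ratio of ubiquitin went the other way, by 0.51 (exact permutation p = 0.035, adjusted p = 0.061), as did that of EF1a, by 0.36 (exact permutation p = 0.11). For GAPDH the difference was -0.05 (exact permutation p = 0.80) and for cyclophilin 0.01 (exact permutation p = 0.96). Scaling the arrays to the added transcripts moved the median change of all probe sets from 0.15 to -0.53 log2 units. That scaling was chosen after the data were examined.

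**Figure D1:**
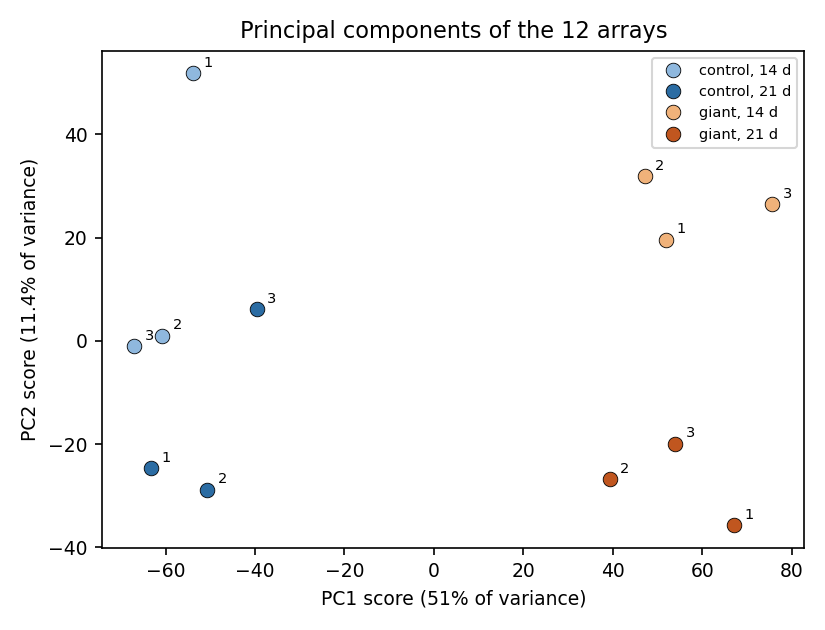
Scores of the 12 arrays on the first 2 principal components (51% and 11.4% of the variance), each point an array and each colour a group. Giant-cell arrays lay between 39.3 and 75.7 on the first component and control arrays between -67 and -39.6.

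The first comparison asked how giant cells differed from control cells, averaged over both days. The largest rise among named genes was that of a gene of starch synthesis, and several of the deepest falls were those of water-channel genes. SBE1 (Gene ID 542238, synonyms ae1 and SBEIIb), a starch branching enzyme gene, was 24.2-fold higher (log2 4.60 ± 0.32 SE, n = 6 arrays per cell type, limma adjusted p = 1.2e-06), with mean signals of 24.9 and 21.8 in control cells and 850.0 and 721.0 in giant cells at 14 and 21 days. The aquaporin gene por2 (Gene ID 541687, synonym TIP2-3) was 65.7-fold lower (log2 -6.04 ± 0.34, adjusted p = 1.6e-07), and NNR1 (Gene ID 542278), a nitrate reductase gene, 22.1-fold lower (-4.47 ± 0.59, adjusted p = 0.00014). Each of these genes had all 3 giant-cell arrays on the same side of all 3 control arrays on both days. The naming rule required this, and 2798 of all probe sets tested met it. Of the 12080 probe sets tested, 3038 were higher and 2054 lower in giant cells, and 1127 and 1320 of these differed at least 2-fold. Among the 790 named genes tested, 170 rose and 197 fell.

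After SBE1, the largest rises among named genes whose giant-cell arrays all lay above the control arrays on both days were those of prcw1 (3.55 ± 0.33), the glutamine synthetase gene gln2 (2.89 ± 0.33), zmCL2-2 (2.87 ± 0.51), AGP2 (2.85 ± 0.51), a subunit of ADP-glucose pyrophosphorylase, GRF8 (1.97 ± 0.28) and the cellulose synthase gene CesA-3 (1.96 ± 0.19). Next came hdr10 (1.94 ± 0.16), the knotted-class homeobox gene lg3 (1.94 ± 0.47), sdx1 (1.93 ± 0.43), the malate dehydrogenase gene mdh6 (1.83 ± 0.30) and the starch synthase gene ss1 (1.82 ± 0.28). The phototropin gene nph1 rose by 2.08 (adjusted p = 0.0035), but its arrays overlapped. The adjusted p-values of the other 11 genes lay between 5.9e-06 for hdr10 and 0.0055 for lg3. All 12 rises, SBE1 included, kept their direction and stayed past the threshold when the arrays were scaled to the added control transcripts. With that scaling, 123 of the 170 named rises kept their sign and 28 stayed past the threshold, and the split of all called probe sets moved from 3038 higher and 2054 lower to 456 higher and 5050 lower.

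Beyond por2 and NNR1, the deepest falls among named genes whose giant-cell arrays all lay below the control arrays on both days were those of the glycine-rich protein gene grp3 (-6.15 ± 0.45, 70.9-fold), cyclotide (-5.74 ± 1.00), and the aquaporin genes PIP2-4 (-5.33 ± 0.44), TIP2-2 (-5.23 ± 0.28) and TIP2-1 (-4.60 ± 0.44). The auxin influx carrier gene aic1 (synonym aux1) fell by 4.78 on the log2 scale (± 0.52), and its mean giant-cell signals of 1.75 and 3.92 lay below the offset of 9.5 added to every signal, so that this fold is compressed. For grp3 the mean giant-cell signal at 21 days (8.93) was below it too, and single arrays were below it for cyclotide, NNR1, aldh5 and gst23 in giant cells and for SBE1, AGP2 and sdx1 in control cells. Further falls were those of the aldehyde dehydrogenase gene aldh5 (-4.46 ± 0.65), the silicon channel gene Lsi1 (-4.31 ± 0.45), the asparagine synthetase gene AS (-4.23 ± 0.62, with a dimmer probe set at -1.96 and adjusted p = 0.033) and the glutathione transferase gene gst23 (-3.85 ± 0.51). Adjusted p-values of the 12 falls ran up to 0.0008, that of cyclotide. The gene al1 fell by 6.35 on the log2 scale (adjusted p = 0.00015), but its arrays overlapped.

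**Figure D2:**
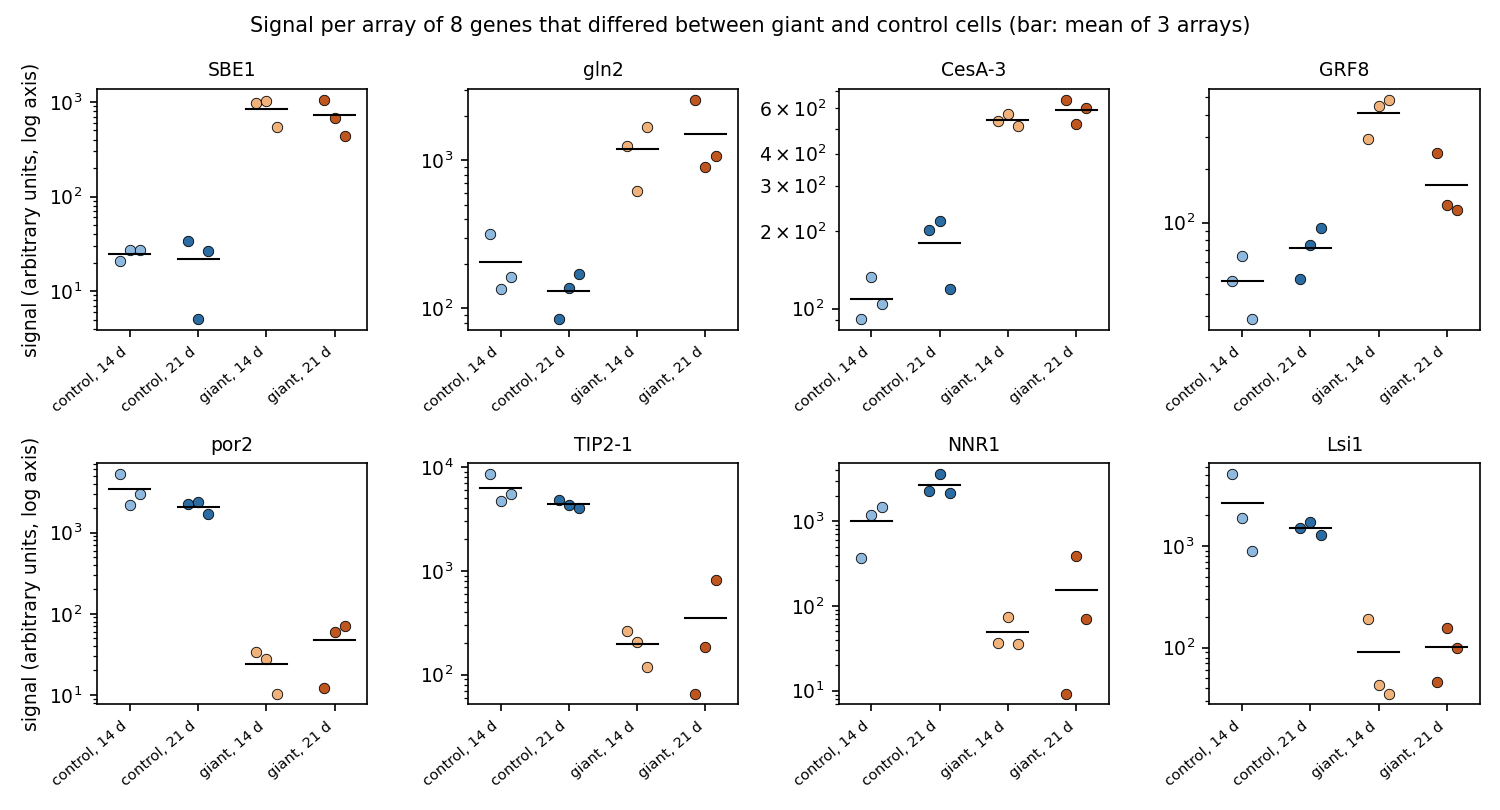
Signal of 8 named genes on each array (log axis, arbitrary units), 1 panel per gene and 1 column per group, with a bar at the mean of the 3 arrays. SBE1, gln2, CesA-3 and GRF8 lay higher in giant cells on both days, with mean SBE1 signals of 850.0 and 721.0 against 24.9 and 21.8, and por2, TIP2-1, NNR1 and Lsi1 lay lower.

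Aquaporins as a group were lower in giant cells. Of 21 members tested, 12 fell, 2 rose and 7 did not pass, with a median log2 change of -1.69 (camera adjusted p = 0.0014, and adjusted p = 0.31 with an estimated correlation). The fallers included members of the plasma membrane, tonoplast and NIP classes, such as PIP1-5 (-2.92) and pip2-5 (-2.87), and the genes that rose were PIP1-3 (0.82, adjusted p = 0.033) and TIP4-1 (1.29, adjusted p = 0.025). Adjusted over the list alone, 12 fell and 3 rose. Sucrose and sugar transport and cleavage genes were also lower: 5 of 6 fell and none rose, with a median of -1.77 (camera adjusted p = 0.04, and adjusted p = 0.31 with an estimated correlation). They were the monosaccharide transporter gene MST1 (-3.75), the invertase genes ivr2 (-3.57) and incw1 (-2.12), and the sucrose synthase genes SH-1 (-1.42) and ss2 (-1.23). The sucrose synthase gene sus2 stood at 0.79 (adjusted p = 0.055). In the test adjusted over the list alone, 5 fell and 1 rose. In the mean of both days, tissue markers moved with the cell type beside both groups. Of 4 xylem markers 3 fell (median -2.52). All tested markers of root meristem and cap (2 genes, median 1.74) and of lateral root primordia (4 genes, median 1.06) rose. At 14 days alone the numbers past the threshold were 3, 2 and 3, and at 21 days alone 0, 0 and 1. List medians kept their direction on both days. With scaling to the added transcripts, the 3 xylem falls, lg3 and GRF8 stayed past the threshold. The other rises did not: rs2 (0.94, limma adjusted p = 0.052), GRF4 (0.48, 0.12), GRF2 (0.34, 0.4) and GRF12 (0.2, 0.71). The camera p of the sugar list was above the threshold without array 1 of control cells at 14 days (0.063), array 3 of control cells at 21 days (0.053) or array 2 of giant cells at 21 days (0.058), with quantile normalization (0.052), with no filter (0.06) or a stricter one (0.12), and with scaling to the added transcripts (0.13).

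None of the other 17 lists tested passed with camera in this comparison. Among glutathione transferases and antioxidant enzymes, 12 of 28 fell and 3 rose (median -0.81, camera adjusted p = 0.11), and adjusted over the list alone 12 fell and 4 rose. Gene gst2 (-3.22, adjusted p = 8.7e-06) and gst31 (-2.50) fell, and the ascorbate peroxidase gene apx rose (1.49, adjusted p = 2.5e-05), whereas the rises of sod3 (0.55) and trxh1 (0.41) turned negative with scaling to the added transcripts. Cytokinin and gibberellin genes had 6 of 11 lower and 0 higher (median -0.71, adjusted p = 0.11), among them the cytokinin response regulators crr1 (-2.02) and RR9 (-0.69) and the zeatin glucosyltransferase gene ciszog1 (-2.20). Adjusted over the list alone, 7 fell and 1 rose, and without array 2 of giant cells at 14 days the list passed (adjusted p = 0.047). Oxylipin and jasmonate genes had 4 of 9 lower and 2 higher (median -0.82, adjusted p = 0.37). The lipoxygenase genes lox1 (-2.02) and lox3 (-1.89) and opr5 (-2.26) fell, opr8 rose (0.75), and the rise of aoc1 (0.55) turned negative with scaling to the added transcripts. All 3 tested class III peroxidases fell, PER2 (-3.97), pmPOX1 (-1.18) and ap1 (-3.25), though the name ap1 belongs to another kind of gene. Lists with fewer than 5 tested members, as here, had no list test.

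Cell wall genes moved both ways. Of 14 cellulose synthases and other wall polysaccharide genes, 8 fell and 2 rose (median -0.87, camera adjusted p = 0.37): bk2 (-2.53) and CesA-2 (-1.29) fell, while CesA-3 (1.96) and CesA-5 (0.74, adjusted p = 0.008) rose. The list of xylem markers shares 3 cellulose synthase genes of secondary walls with it, cesa10 (-3.28), cesa11 (-2.54) and CesA12 (-2.51). All 3 fell, and the laccase gene LAC1 stood at 0.40 (adjusted p = 0.28). Expansins and xyloglucan endotransglucosylases had 3 of 7 lower and 1 higher (median -1.38, adjusted p = 0.40), with expa1 (-2.58) and EXPA5 (-2.19) lower and expA4 (1.83) higher. Of 6 phenylpropanoid and lignin genes, ccr2 fell (-1.71) and 5 did not pass (median -0.52, adjusted p = 0.79). In the cytoskeleton list, 7 of 17 fell and 3 rose (median -0.11, adjusted p = 0.66). The tubulin genes tua6 (-1.69), tub5 (-1.55) and tub4 (-2.12) fell, and the profilin genes PRO4 (0.91) and prf5 (0.76) and the tubulin gene TUBB2 (1.36) rose. In the test adjusted over the list alone, 8 fell and 3 rose. The ratio of 3′ to 5′ actin signal, a measure of transcript integrity, moved with the cell type by -1.77, as given above.

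**Figure D3:**
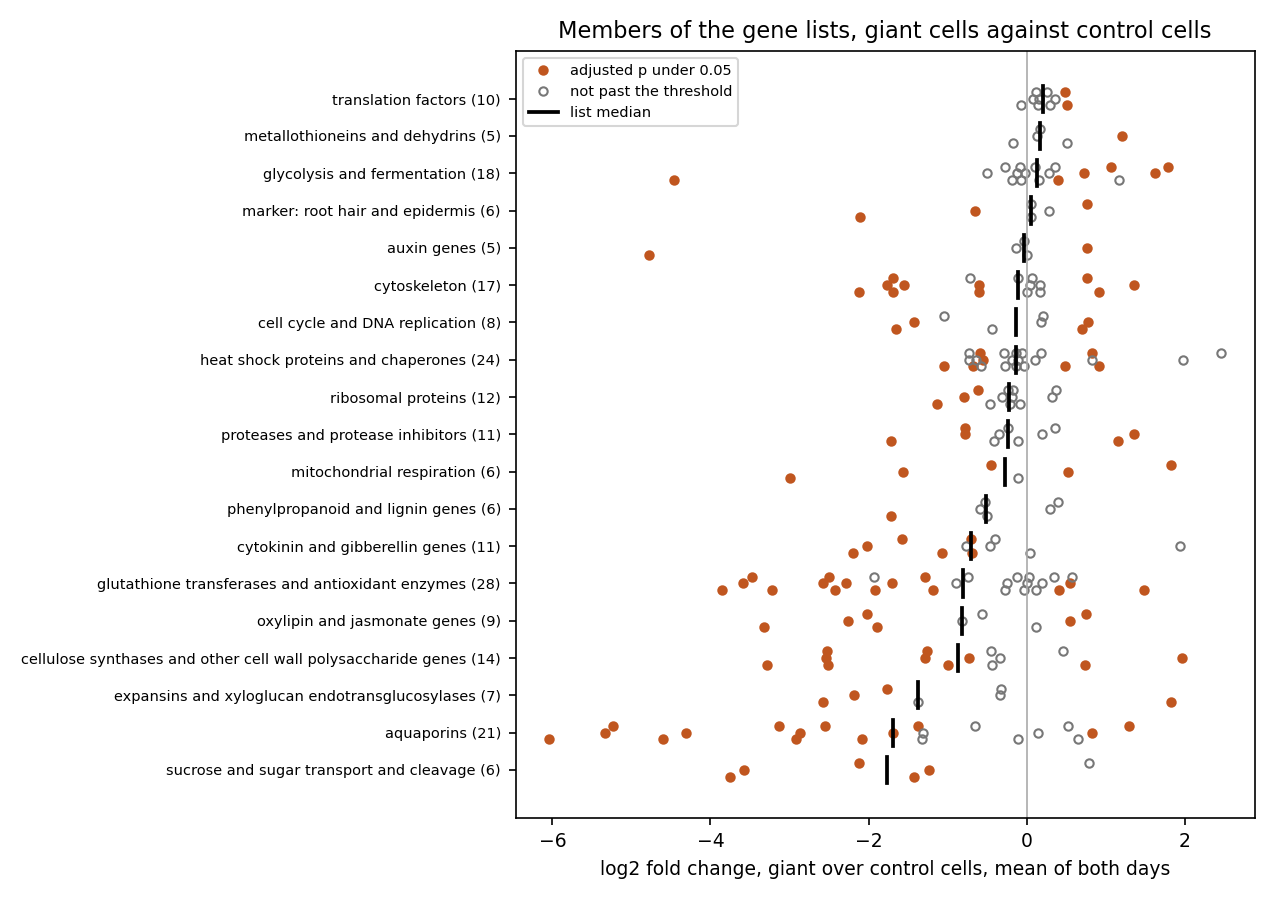
Log2 fold change of giant over control cells (mean of both days) for each tested member of 19 gene lists, filled where adjusted p was under 0.05, with a bar at the list median and the number of members in brackets. Sugar genes (median -1.77) and aquaporins (-1.69) had the lowest medians, and of the filled rises those of elfa2, elfa3, aoc1, eno1, CYTMDH, pdi12, sod3 and trxh1 turned negative with scaling to the added control transcripts.

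Of 18 glycolysis and fermentation genes, 5 rose and 1 fell (median 0.13, camera adjusted p = 0.40). Of the 18, 5 have names that belong to another kind of gene. The alcohol dehydrogenase gene adh1 (1.79), the pyruvate decarboxylase genes pdc2 (1.62) and pdc3 (0.72) and the glyceraldehyde phosphate dehydrogenase gene GAPC1 (1.07) rose. The rise of eno1 (0.40) turned negative with scaling to the added transcripts, and the faller was the aldehyde dehydrogenase gene aldh5. A dimmer probe set of GAPC1 stood at 0.67 (adjusted p = 0.069). In the respiration list 3 of 6 fell and 2 rose (median -0.28, adjusted p = 0.79). The alternative oxidase gene Aox fell (-3.0), as did ATP2 (-0.45), while the genes that rose, mdh6 (1.83) and CYTMDH (0.52, negative with scaling to the added transcripts), encode malate dehydrogenases and not parts of the respiratory chain. Ribosomal protein genes had 3 of 12 lower (median -0.22, adjusted p = 0.45), rpl30 (-1.13), L29 (-0.79) and rps6-2 (-0.62). At 21 days 2 arrays bore on L29, which did not pass without array 2 of control cells (adjusted p = 0.067) or array 1 of giant cells (0.054). Translation factors had 2 of 10 higher (median 0.21, adjusted p = 0.29), elfa2 (0.49) and elfa3 (0.51), and both turned negative with scaling to the added transcripts.

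Cell cycle and DNA replication genes had 2 of 8 higher, the origin recognition gene orc1 (0.77) and the retinoblastoma-related gene RBR1 (0.70), and 2 lower, PCNA (-1.65) and pcna2 (-1.43), which encode the sliding clamp of DNA replication. The fall of pcna2 was not past the threshold without any 1 of 6 arrays (adjusted p up to 0.064). The median was -0.13 and the mean -0.34, whereas camera ranked the list upward (adjusted p = 0.90). Of 4 core and linker histone genes, hon101 (1.09) and his1a (0.67, negative with scaling to the added transcripts) rose and H1 fell (-0.41, adjusted p = 0.047, up to 0.11 without single arrays). Dimmer probe sets of H1 stood between -0.45 and -0.32, and none of them passed (limma adjusted p from 0.10 to 0.22). Of 8 genes with GRF symbols, taken as a marker list for lateral root primordia, 4 were tested and these 4 rose: GRF8 (1.97), GRF4 (1.14), GRF2 (0.99) and GRF12 (0.87, adjusted p = 0.048, up to 0.11 without single arrays). Both tested markers of root meristem and cap, the homeobox genes lg3 (1.94) and rs2 (1.54), rose. Root hair and epidermis markers had 1 of 6 higher, rbohB (0.76), and 2 lower, rop6 (-2.11) and LOC542739 (-0.65). That median was 0.05 against a mean of -0.27 and a downward camera test (adjusted p = 0.90). Both tested genes matched as phloem markers, PP2C (0.69, adjusted p = 0.063) and pp2c-1 (0.39, adjusted p = 0.087), have names of protein phosphatases and did not pass, though adjusted over the list alone both rose. Without array 3 of control cells at 21 days, PP2C passed (adjusted p = 0.0064) and so did pp2c-1 (0.047), and without array 1 of control cells at 14 days their adjusted p-values were 0.029 and 0.033. The photosynthetic tissue marker C4ppdkZm1 stood at -0.26 (adjusted p = 0.42).

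Stress and hormone lists were mixed. Heat shock proteins and chaperones had 3 of 24 higher and 4 lower (median -0.14, mean 0.04, downward camera test with adjusted p = 0.90). Genes pdi4 (0.91) and pdi3 (0.83) rose, pdi6 (-0.68) and pdi8 (-1.04) fell, and the rise of pdi12 (0.49) turned negative with scaling to the added transcripts. In the test adjusted over the list alone, 3 rose and 3 fell. At 14 days hsp22, hsp18f, hsp18c and hsp101 were higher on array 3 of both cell types than on any other array, with hsp22 at signals of 7000 and 2820 against at most 975. HSP18 stood apart on the control array alone (6500), with 479 on the giant-cell array and at most 481 elsewhere. Proteases and protease inhibitors had 2 of 11 higher, the cystatin genes cc3 (1.36) and cc7 (1.15), and 3 lower, among them ccp2 (-1.71) and mir2 (-0.78), with a median of -0.23 and an adjusted p of 0.90. Of 5 metallothioneins and dehydrins EMB5 rose (1.20, adjusted p = 0.039, up to 0.093 without single arrays), with a list median of 0.17 and a camera adjusted p of 0.66, and adjusted over the list alone none passed. Auxin genes had 1 of 5 higher, abp1 (0.76), and 1 lower, aic1 (-4.78), with a median of -0.03 and an adjusted p of 0.88. Of these 5, 2 have names that belong to another kind of gene. Of 2 ethylene genes acco20 rose (1.56), and of 3 benzoxazinoid genes glu1 fell (-3.27) and igl1 rose (0.75). The nitrate transporter gene nrt2 (-3.34) and the phosphate transporter gene pht1 (-1.68) fell among 3 nitrogen, peptide, metal and phosphate transporters. None of 3 pathogenesis-related genes passed, with chitinase at 1.73 (adjusted p = 0.26, but 2.98 and 0.0098 without array 3 of giant cells at 14 days), PR-5 at -0.32 and sip1 at -0.65 (median -0.32, mean 0.26). None of 3 WRKY, MYB, NAC and bHLH genes passed either, with MYB38_1 at -0.76 (adjusted p = 0.13), a median of 0.26 and a mean of -0.06. Adjusted over the list alone, every list for which no such count is given had the same counts as over all genes tested.

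At 14 days the comparison of giant with control cells asked what differed at the earlier stage. SBE1 was 24.2-fold higher (4.59 ± 0.45, n = 3 arrays per group, limma adjusted p = 6.7e-05), followed by prcw1 (3.64 ± 0.46), AGP2 (3.35 ± 0.72), the phototropin gene nph1 (3.12 ± 0.65, adjusted p = 0.005) and zmCL2-2 (2.98 ± 0.72). Among the falls taken by the naming rule, por2 was 103-fold lower (-6.69 ± 0.48, adjusted p = 5.6e-06), followed by cyclotide (-5.60 ± 1.41), PIP2-4 (-5.60 ± 0.62), grp3 (-5.49 ± 0.64) and TIP2-2 (-5.38 ± 0.40). A probe set of IIG1, which the rule did not take, stood at -6.27 (± 0.38, limma adjusted p = 2.1e-06). Of the aquaporins 12 of 21 fell and 0 rose (camera adjusted p = 0.00026, and adjusted p = 0.27 with an estimated correlation), or 13 and 1 adjusted over the list alone. Of the sugar genes 5 of 6 fell (adjusted p = 0.049, and adjusted p = 0.27 with an estimated correlation), and 5 fell adjusted over the list alone. In all, 1872 probe sets were higher and 1452 lower, and 105 named genes rose and 155 fell. Without array 3 of giant cells cyclotide was no longer past the threshold (adjusted p = 0.056) and the 3324 calls became 2085, and without array 3 of both cell types, a choice made after the data were examined, 1344, with AGP2, zmCL2-2 and cyclotide no longer past it (adjusted p = 0.065, 0.092 and 0.084). With scaling to the added transcripts, 344 were higher and 2496 lower.

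At 21 days the same comparison addressed the later stage. SBE1 (4.60 ± 0.45, 24.3-fold, n = 3 arrays per group, limma adjusted p = 6.8e-05), prcw1 (3.46 ± 0.46), gln2 (3.33 ± 0.46), zmCL2-2 (2.77 ± 0.72) and mdh6 (2.65 ± 0.42) rose most among named genes whose groups did not overlap. The gene al1 fell by 7.89 on the log2 scale (± 1.19, adjusted p = 0.0014), from a mean signal of 3790 to 4.38, a value below the offset. The giant-cell signals of grp3 (-6.80 ± 0.64, signal 8.93) and aic1 (-5.60 ± 0.73, signal 3.92) lay below the offset as well, as did 2 of the 3 giant-cell arrays of cyclotide (-5.87 ± 1.41), so that the sizes of these falls, and their order, depend on it. The gene por2 fell too (-5.39 ± 0.48). Of the aquaporins 11 of 21 fell and 0 rose (camera adjusted p = 0.002, and adjusted p = 0.34 with an estimated correlation), with the same counts adjusted over the list alone. Of the sugar genes 5 of 6 fell (adjusted p = 0.02, and adjusted p = 0.34 with an estimated correlation), or 5 fell and 1 rose adjusted over the list alone. In all, 1163 probe sets were higher and 1054 lower, and 75 named genes rose and 119 fell. The 2217 calls became 1038 without array 1 of giant cells, 1075 and 1214 without array 1 and array 2 of control cells, and 1255 without array 3 of giant cells. Without some of these arrays cyclotide and zmCL2-2 did not pass (adjusted p up to 0.066 and 0.083). With scaling to the added transcripts there were 3673, of which 135 were higher and 3538 lower.

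Whether the giant-cell effect differed between the days was tested directly. Most probe sets called on both days went the same way: 739 were higher on both days, against 180 if the calls were independent, 758 were lower on both, against 127, and 3 went opposite ways. The changes on the days had a correlation of 0.81 across probe sets, which are not independent replicates. No probe set passed the limma test of the difference, with 839 at an unadjusted p under 0.05 and a smallest adjusted p of 0.207. Named genes nearest to it were the linker histone gene H1 (-1.69 ± 0.31, adjusted p = 0.21), ROA (-3.26 ± 0.65, adjusted p = 0.31), whose name stands for replication origin activator, and pht7 (3.48 ± 0.75, adjusted p = 0.31), a phosphate transporter gene by its symbol, with n = 3 arrays per group. Without array 2 of giant cells at 21 days, 9 probe sets passed. On simulated data with changes of 2 log2 units in the difference, 86 of 200 were recovered, and of changes of 1 unit none was.

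**Figure D4:**
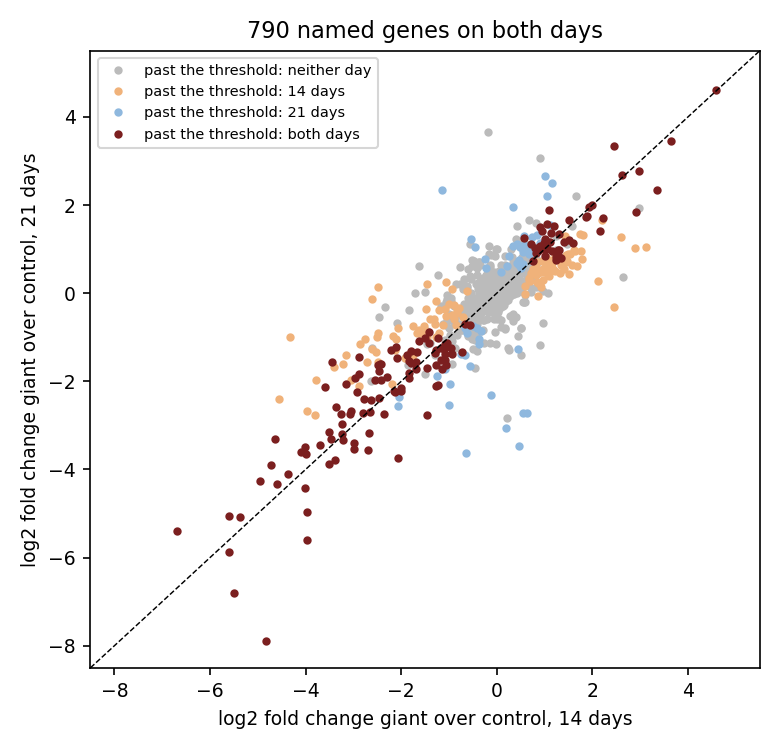
Log2 fold change of giant over control cells at 14 days (horizontal) and 21 days (vertical) for the 790 named genes tested, each point a gene coloured by the days on which it was past the threshold, with a dashed line where both are equal. Across all 12080 probe sets the correlation was 0.81.

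As groups, 4 lists passed camera for the difference between days. Cell cycle and DNA replication genes had a lower giant-cell effect at 21 days than at 14 days (median -0.66, camera adjusted p = 0.0025, and adjusted p = 0.29 with an estimated correlation). Values were lowest for MCM6 (-3.35 ± 0.90, adjusted p = 0.47) and MCM7 (-1.91 ± 0.80, adjusted p = 0.68), which encode subunits of the replicative helicase, and for pcna2 (-3.25 ± 0.93, adjusted p = 0.49). None of the 8 passed over all genes tested, and 2 were lower adjusted over the list alone. Cytoskeleton genes (median 0.47, adjusted p = 0.017, and adjusted p = 0.53 with an estimated correlation), phenylpropanoid and lignin genes (0.89, adjusted p = 0.034, and adjusted p = 0.46) and metallothioneins and dehydrins (1.01, adjusted p = 0.048, and adjusted p = 0.29) had a higher effect at 21 days. None of their members passed over all genes tested, and 1 phenylpropanoid gene passed adjusted over the list alone. With fry none of the 4 lists passed (adjusted p = 0.17, 0.31, 0.28 and 0.13, in the order given). Tissue markers, in lists too small for a list test, shifted beside these lists. Their medians were 1.06 for xylem, -0.53 for lateral root primordia and -0.47 for root meristem and cap, and no marker of these passed over all genes tested. From 14 to 21 days the median changes of these markers were 0.07, -0.52 and -0.26 in giant cells. In control cells they were -1.26, 0.18 and 0.21, so the xylem shift lay mostly in control cells. The median change of the phenylpropanoid list was 0.42 in giant cells and -0.89 in control cells. The cell cycle list passed without each array in turn. The cytoskeleton list did not without array 1 of control cells at 14 days (0.16) or, at 21 days, array 3 of control cells (0.16) or array 2 of giant cells (0.078). Without those same 3 arrays the phenylpropanoid list had adjusted p-values of 0.16, 0.054 and 0.10, with 0.11 without array 3 of giant cells at 14 days and 0.078 without array 3 of giant cells at 21 days. Metallothioneins and dehydrins passed only without array 1 or 2 of control cells at 21 days, array 1 of giant cells at 14 days or array 1 of giant cells at 21 days.

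Between 14 and 21 days giant cells changed in few named genes. The phosphate transporter gene pht7 (Gene ID 732717) was 16.3-fold higher at 21 days (4.02 ± 0.53, n = 3 arrays per day, limma adjusted p = 0.0088), from a mean signal of 137 to 2160. The cystatin gene cc7 (1.85 ± 0.38, adjusted p = 0.049), the beta-tubulin gene tub7 (0.81 ± 0.17, adjusted p = 0.049) and LOC542610 (1.99 ± 0.29, adjusted p = 0.012), which has no other name in the tables, also rose. ROA fell by 2.58 on the log2 scale (± 0.46, adjusted p = 0.029). The aquaporin gene PIP2-1 (-1.79 ± 0.28, adjusted p = 0.015) and EMF-like (-1.19 ± 0.24, adjusted p = 0.045; synonym vef101), a Polycomb group gene, fell as well. In each of these 7 genes the 3 arrays of a day did not overlap those of the other, which chance gives in 10% of such comparisons. The naming rule required this, so it is no further evidence, and 3118 of the 12080 probe sets tested met it. In all, 33 probe sets were higher and 44 lower. The split was 82 higher and 44 lower with a common 75th percentile. PIP2-1 and LOC542610 have dimmer probe sets, which were set beside the main ones in the mean contrast alone. There that of PIP2-1 stood at -0.39 (limma adjusted p = 0.22) against -1.69. Those of LOC542610 stood between -0.34 and -0.10 against 0.23, with none past the threshold.

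Ribosomal protein genes were higher at 21 days in giant cells as a group (median 0.49, camera adjusted p = 0.0096, and adjusted p = 0.71 with an estimated correlation), as were metallothioneins and dehydrins (1.07, adjusted p = 0.014, and adjusted p = 0.22), and cell cycle genes were lower (-0.48, adjusted p = 0.019, and adjusted p = 0.71). No member of these lists passed singly over all genes tested. ROA, whose name stands for replication origin activator, was not matched to the cell cycle list but fell in the same comparison (-2.58, limma adjusted p = 0.029). Adjusted over the list alone, 2 ribosomal protein genes and 1 of the metallothioneins and dehydrins were higher and 3 cell cycle genes lower. The count of 77 probe sets depended on single arrays: it was 4 without array 1 of giant cells at 21 days, when pht7 had an adjusted p of 0.058 and ROA of 0.12, 15 without array 3 of the same group, and 9 and 13 without array 2 and array 3 of giant cells at 14 days. Through the shared estimate of the spread it was 205 and 37 without array 1 and array 2 of control cells at 14 days, and 44 without array 2 of control cells at 21 days.

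**Figure D5:**
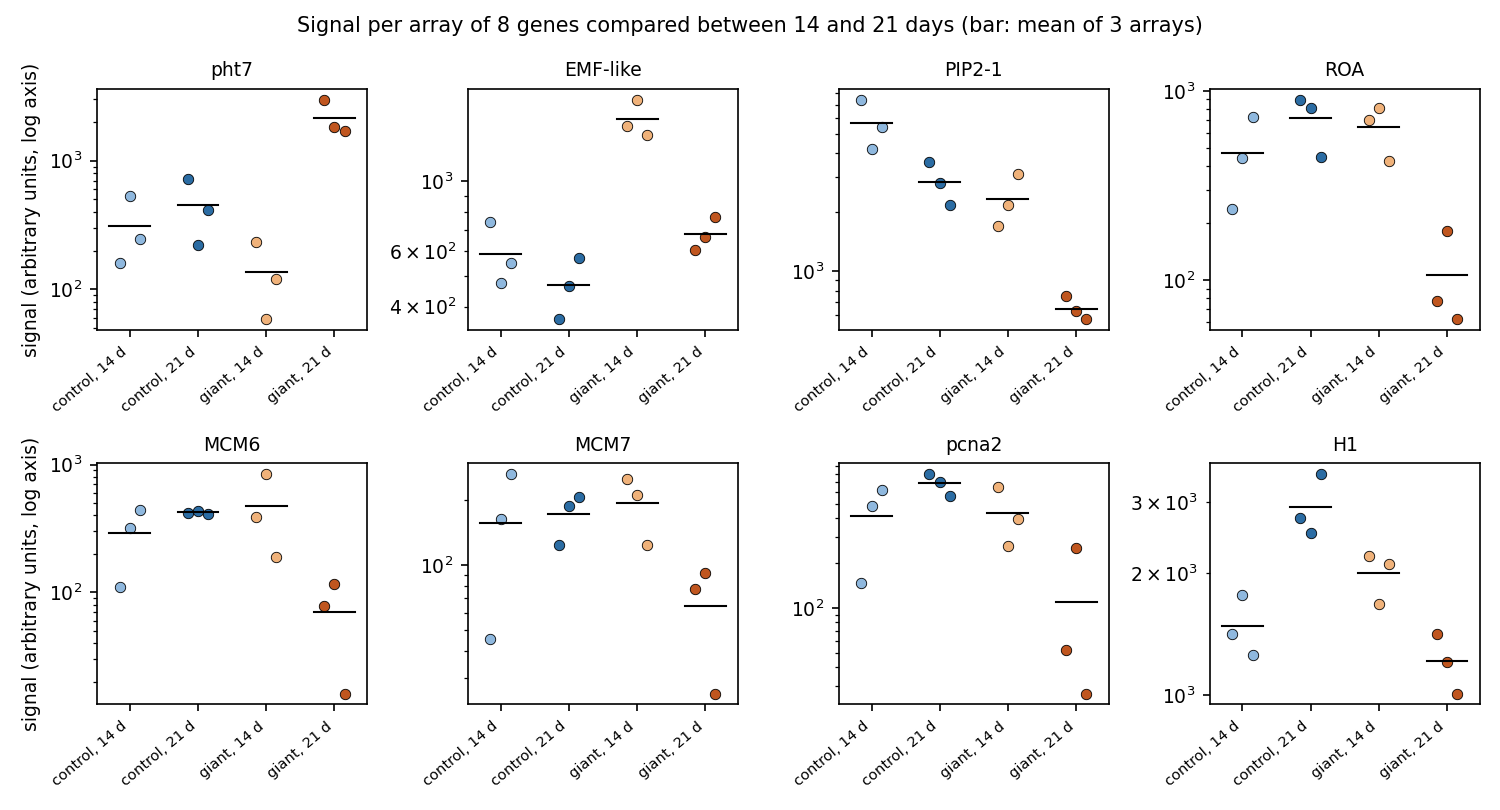
Signal of 8 genes on each array (log axis, arbitrary units), 1 panel per gene and 1 column per group, with a bar at the mean of the 3 arrays. In giant cells pht7 went from a mean of 137 at 14 days to 2160 at 21 days and ROA from 645 to 107, whereas the differences between days of MCM6, MCM7, pcna2 and H1 were not past the threshold.

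Control cells gave a background for change with time outside giant cells. No named gene passed between 14 and 21 days. The nearest were Sal1 (-0.89 ± 0.18, n = 3 arrays per day, limma adjusted p = 0.23), the aquaporin gene PIP2-6 (-2.30 ± 0.50, adjusted p = 0.24) and H1 (0.97 ± 0.22, adjusted p = 0.24). The probe sets that passed numbered 3, all without a gene name in the annotation used and all higher at 21 days, with log2 changes of 2.31, 1.74 and 1.02. They were singled out after their values were seen, and each was also past the threshold and higher at 21 days in giant cells (2.86, 1.87 and 1.96, in the same order). Ribosomal protein genes were higher as a group (median 0.43, camera adjusted p = 0.0015, and adjusted p = 0.53 with an estimated correlation) and aquaporins lower (-0.48, adjusted p = 0.044, and adjusted p = 0.53). None of their members passed over all genes tested, and adjusted over the list alone 1 ribosomal protein gene was higher and 2 aquaporin genes lower. The count of 3 became 0 without array 1 or array 2 of control cells at 21 days, and 1 or 2 without any of the other arrays.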

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

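Tests of the hybridization controls, of the heat shock genes, and of the cell cycle list with an estimated correlation were chosen after the result was seen, as were scaling to hybridization controls and leaving out the day-14 arrays numbered 3.

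The hybridization control transcripts, which lie outside the gene comparisons, were brighter on giant-cell arrays by 0.70 log2 units and the 18S probe sets by 0.80. A candidate explanation is the authors' scaling of every array to 1 trimmed mean when giant-cell arrays were dimmer before it, which needs all added transcripts to shift alike: the smallest shift among bioB, bioC, bioD and cre was 0.67 and the largest 0.74. Other differences in brightness between whole arrays would shift them alike too, so these shifts do not single out the authors' scaling. With arrays scaled to these transcripts, 8.28% of calls in the mean contrast were higher against 59.7% as deposited. This moved the median of all probe sets from 0.15 to -0.53, so fewer rises followed from it, which is no test of the authors' scaling. The share of rises and the direction of small rises thus depend on how the arrays are scaled. Raising dimmer arrays raises signals, so no test of the authors' scaling was made for the lower aquaporin and sugar genes. Their list medians were -1.69 and -1.77 as deposited and -2.39 and -2.46 with scaling to the added transcripts. A lower RNA content of the smaller captured area stays open, because captured area and cell type go together in this design, and a biological difference in the RNA content of giant cells was not tested.

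Heat shock genes stood above the other arrays on the day-14 arrays numbered 3, 4 of 5 of them in both cell types: hsp22 had signals of 7000 in control cells and 2820 in giant cells against at most 975 elsewhere, and hsp101 2560 and 3580 against at most 656, whereas HSP18 stood apart in control cells alone (6500, with 479 in giant cells and at most 481 elsewhere). Giant cells in the control sample are argued against for these 5 genes alone, which were chosen after their values were seen. Their median was 1.44 log2 units higher on the control array than on the giant-cell array, though hsp101 went the other way (-0.48). Genes called higher in giant cells at 14 days lay at a median of -0.22 on the control array, against the other control arrays of that day. That array took part in calling them, so this value is no test. Control cells in the giant-cell sample were not tested. A batch or plants shared by these arrays could not be told from chance: away from the heat shock genes their deviations had a correlation of 0.10 across probe sets, while the highest other pair of that day had 0.17. A response of the plants to heat or handling may also have been present, and the design names no such factor.

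Cell cycle and DNA replication genes had a giant-cell effect lower at 21 than at 14 days, by a list median of -0.66. That it came from 1 array is argued against, since the median stayed between -0.84 and -0.46 without each array in turn, with adjusted p-values from 0.00057 to 0.028. Scaling to the hybridization controls gave no test of the authors' scaling, since it moved the median of all probe sets from -0.03 to -0.24, so that the list, at -0.87 with it, went lower with the rest. A few genes that move together stay open, since the adjusted p was 0.29 with an estimated correlation, which is what keeps this from being told apart from a change of the whole group. With fry the cell cycle list did not pass either (adjusted p = 0.17). That giant cells replicate DNA less at 21 days is a hypothesis that these data could not settle, and 18 of 100 splits of the arrays gave at least the 4 lists that passed for this difference.

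The giant-cell effect also differed between days by list medians of 0.47 for cytoskeleton genes, 0.89 for phenylpropanoid and lignin genes and 1.01 for metallothioneins and dehydrins. For phenylpropanoid and lignin genes the median change from 14 to 21 days was 0.42 in giant cells and -0.89 in control cells. None of these list calls held in camera with an estimated correlation (adjusted p = 0.53, 0.46 and 0.29), and none of the lists passed with fry (adjusted p = 0.31, 0.28 and 0.13). No member passed over all genes tested, and each list lost its call without some single arrays. For tub7 (0.77) and mtl2 (1.22), all giant-cell arrays of a day lay on the same side of the control arrays and those of the other day on the opposite side, but the test of the difference gave adjusted p-values of 0.51 and 0.63.

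In the mean contrast 1 of the 100 splits drawn from the 200 possible within days gave as many calls, the real one with 5092 against at most 1736. A split that mixes the cell types puts their difference into the spread within groups, which lowers its count. The real split stood alone among those drawn, which makes chance unlikely but does not exclude it. For the difference between days, with 0 calls, all 100 of 100 splits gave at least as many by construction, so that the comparison says nothing about chance. The highest, 5092, came from the split that swaps the cell types on one of the days, which is the mean contrast itself. The 2 lists of the mean contrast were matched by 61 of 100 splits, with at most 8, so chance was not excluded for the number of lists, nor for the 4 lists of the difference between days, where 8 was also the highest. At 14 days and at 21 days the real split alone, 1 of 10, gave as many calls, 3324 against at most 0 and 2217 against at most 0. Between days it was 1 of 10 as well, with 77 against at most 3 in giant cells and 3 against at most 2 in control cells, and 10 splits are too few for a share under 0.05.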

How the results depend on the processing

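Scaling to hybridization controls, leaving out both day-14 arrays numbered 3 and lists without mismatched names were added after the data were examined. Values of the genes taken by the naming rule stayed on the same side of the threshold in 3700 cases over all alternatives, with 165 no longer past it and 24 newly past it. Among the 3700, 29 values that were past it in neither fit changed sign, 12 of them with scaling to hybridization controls. A further 4 that were past it in at least 1 of the fits changed sign, in the mean contrast and under that scaling: elfa2 (-0.22), elfa3 (-0.19), eif5a (-0.44, adjusted p = 0.022) and his1a (-0.03). For list values 496 stayed on the same side, 13 of them with a change of sign, 36 were no longer past it, 9 newly past it, and 0 changed sign while past it. Unless a construction is named, the cause was not tested.

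The count of the mean contrast (5092) was 2447 with at least a 2-fold change and 364 with 1 probe set per gene, which tests fewer probe sets. That alternative gave 263 at 14 days, 197 at 21 days, 10 between days in giant cells and 0 in control cells. Between days, 77 probe sets in giant cells and 3 in control cells became 201 and 5 with the offset at the 40th percentile, 118 with quantile normalization (giant cells), 126 and 1 with a common 75th percentile, 42 and 1 with no filter, 48 and 1 with no variance trend, 310 and 9 with array weights, and 0 in control cells with only the groups compared. Scaling to hybridization controls gave 3673 at 21 days (135 higher, 3538 lower), 19 between days in giant cells and 0 in control cells, 456 higher and 5050 lower in the mean contrast, and 344 higher and 2496 lower at 14 days. With a common 75th percentile the split between days in giant cells was 82 higher and 44 lower. Without both day-14 arrays numbered 3, which leaves fewer arrays, 1344 passed at 14 days, 11 between days in giant cells and 1 in control cells. The difference between days had 0 under every alternative except leaving out single arrays.

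Of the gene lists, 2 passed as reported, 1 with quantile normalization, 5 with no filter, 1 with the filter above the median on at least 6 arrays, 1 with scaling to hybridization controls, 0 with an estimated correlation and 8 with fry.

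Leaving out each array in turn gave 4288 to 5404 in the mean contrast, 2085 to 3473 at 14 days, 1038 to 2465 at 21 days, 0 to 9 for the difference, 4 to 205 between days in giant cells, 0 to 2 in control cells, and 1 to 3 gene lists. Fewer arrays are part of that construction.

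With a replicate block the counts were 4930 in the mean contrast, 3123 at 14 days, 1910 at 21 days, 0 for the difference, 48 between days in giant cells and 1 in control cells, with 2 lists. Signals near the offset of 9.5, rather than depth, limit folds of dim genes.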

Other observations

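The 3 gene lists below were chosen after the values were seen, so their tests are no independent evidence of direction. Genes of starch synthesis were higher in giant cells as a group: all 7 tested of 16 annotated rose in the mean contrast (median 1.58, camera adjusted p = 0.00013 over these 3 lists, and adjusted p = 0.023 with an estimated correlation). Beside SBE1 (4.60), AGP2 (2.85) and ss1 (1.82) they were GLG1 (1.58), sh2 (1.36 ± 0.27), Agp2 (1.26, a gene apart from AGP2, with the synonym Agpsemzm) and sbe1 (1.11 ± 0.39, adjusted p = 0.035, a gene apart from SBE1). At 14 days 5 rose and at 21 days 4, and with scaling to the hybridization controls 4 of the 7 stayed past the threshold and none fell. SBE1 was bright enough to be tested in giant cells alone, so the filter on signal can favour rises in this list. Genes of nitrate uptake and nitrogen assimilation were lower: 8 of 11 tested fell and 1 rose (median -2.10, camera adjusted p = 0.007, and adjusted p = 0.079 with an estimated correlation). The fallers included NNR1 (-4.47), AS (-4.23), nrt2 (-3.34), the glutamine synthetase genes gln1 (-2.97), GLN6 (-2.16) and gln3 (-1.94) and the glutamate dehydrogenase gene gdh1 (-2.10), and the gene that rose was another glutamine synthetase gene, gln2 (2.89).

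Of 52 tested genes with names of chromatin proteins, 28 rose and 5 fell (median 0.56, camera adjusted p = 6.5e-05, and adjusted p = 0.014 with an estimated correlation), but with scaling to the hybridization controls 1 rose and 12 fell and the median was -0.13, against -0.53 for all probe sets. Rises included the histone deacetylase genes hda113 (1.15 ± 0.15) and hda106 (1.36 ± 0.25) and hac108 (1.20 ± 0.20), and the deepest fall was that of nfd101 (-2.13 ± 0.38). No hypothesis beyond those weighed above was tested on these lists.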
